A study of Arabidopsis thaliana with 8 samples.

How the data were processed

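The deposited files give RPKM for 33590 entries in each of 8 libraries, per the labels and the file headers, with decimal commas. The samples were hand-dissected carpels, and their libraries were made with TruSeq and sequenced on an Illumina HiSeq instrument. The authors' notes name FastQC for read quality and TAIR10 as the reference, and the aligner and the counting program are not given in the sources used here. Sequencing lanes were read from the file headers. Entries without a gene model (6374, all at 0), 18 entries of 9 loci given more than once and 1 malformed entry were left out. Of the 27197 loci used, 26710 matched a locus tag of the reference annotation and 24534 were above 0 in at least 1 library. Coordinates are those of TAIR10.1. Mapped reads per library were recovered from the spacing of low RPKM values and gene lengths, and ranged from 23.1 M to 38.3 M.

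Values were taken as log2(RPKM + 1). Genes at 1 RPKM or more in at least 2 libraries were tested, 17786 in all. One limma model with a mean-variance trend was fitted to all 8 libraries with the 3 groups as terms, and p was adjusted with the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. As the files hold RPKM, tests on read counts could not be made, and the fallback for normalized values stated in the design was used. In a self-test on simulated changes, 50 genes at each size, 52% of 2-fold changes were called in nga against WT, 52% in 35S:NGA against WT and 58% in 35S:NGA against nga. Of 135, 131 and 144 calls there, 11, 5 and 8 were of unchanged genes.

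There were 19 fixed gene lists with 349 genes, and 1 gene was left out because its locus carries another symbol. They covered NGATHA and NGATHA-like genes, style and stigma regulators, auxin synthesis and transport, auxin response, cytokinin, gibberellin, jasmonate, polarity, boundary and meristem regulators, floral MADS-box and ovule regulators, TCP and GRF growth regulators, CYP78A genes, cell cycle, cuticle and epidermis, flavonoid synthesis, tapetum and microspore, mature pollen and green tissue markers, and heat shock and wounding genes. Lists of at least 3 tested genes were tested with camera at its preset inter-gene correlation of 0.01, and again with the correlation estimated from the data and with fry. The NGATHA-like and CYP78A lists, with 2 tested genes each, had no list test. List counts were also made with p adjusted over the list alone.

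Genes were named by a fixed rule. It took the 4 NGATHA genes, the 7 genes in each direction with the largest fold change for comparisons with WT, and 5 in each direction for 35S:NGA against nga. These had to be called, to have a symbol and a mean of at least 5 RPKM in a group, and to have no overlap between the values of the groups compared. It added up to 3 called members of each list by p and up to 6 genes with a symbol per opposite pattern, to which AT5G16030, without a symbol, was joined, 85 genes in all. Genes named outside this rule, such as the clock genes and SPT, were chosen after their values were seen.

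Alternatives fixed before the data were examined were quantile normalization, no filter, a filter at a mean of 5 RPKM, a fit of only the 2 groups compared, the replicate number as a block, pseudocounts of 0.1 and 5, a threshold of at least 2-fold and leaving out each library. Alternatives chosen after the data were seen were the lane as a term, lane 6 only, the fit without the lane 8 libraries and setting the library medians equal. Simulated unchanged groups used 100 draws, with each gene drawn independently, so shifts shared by many genes of a library were not simulated. The tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1. Raw reads were not used here.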

Results

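Transcript levels were measured by RNA sequencing in carpels of Arabidopsis thaliana, ecotype Columbia. The carpels, the organs that form the pistil, were dissected by hand at floral stages 8 to 13 from plants grown on soil in long days, with 15 inflorescences given for each sample. There were 8 libraries in 3 groups. WT had 2 libraries, nga had 3 libraries whose genotype label names the 4 NGATHA genes, and 35S:NGA, an overexpression line, had 3 libraries. NGATHA genes encode B3-domain transcription factors known for their joint part in the development of the style and stigma, the upper end of the pistil. The design compares wild type with loss and with gain of NGATHA function. The label of the overexpression line does not say which NGATHA gene was driven.

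The deposited values were RPKM, reads scaled to gene length and to all mapped reads. Mapped reads, recovered from the smallest steps between low values, came to 36.2 M and 34.2 M in WT, 30.7 M, 38.3 M and 27.0 M in nga, and 23.1 M, 32.5 M and 31.1 M in 35S:NGA. Between 16737 and 17329 loci per library reached 1 RPKM, and the 10 most abundant loci took 4.14% to 5.24% of the summed RPKM. The file headers named the sequencing lanes. WT 1, WT 2, nga 1 and nga 2 ran in lane 6, 35S:NGA 1 and 35S:NGA 2 in lane 7, and nga 3 and 35S:NGA 3 in lane 8, so 35S:NGA shared no lane with WT. A fit with the lane as a term ties 35S:NGA to WT only through 35S:NGA 3 and nga 3, and then nga 1 and nga 2. Without the lane 8 libraries 35S:NGA shares no lane with nga either, so lane and genotype cannot be told apart in its comparisons. The titles number the replicates without saying that they came from separate plants, so the p-values measure only the spread between these samples, which may be technical.

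All tests on single genes were made with limma on log2(RPKM + 1) over 17786 genes with Benjamini-Hochberg adjustment, and a gene was called at an adjusted p under 0.05. Fold changes are log2 differences on that scale with their standard errors, which understate the change of genes at low RPKM. Except where another n is given, n was 2 for WT, 3 for nga and 3 for 35S:NGA. The gene lists, the tests and the rule for named genes were fixed before the data were examined.

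The NGATHA genes were read first in each library. NGA4 (AT4G01500, chromosome 4, 639247 to 640976 in TAIR10.1) stood at 3.97 and 3.83 RPKM in WT and at 0.131, 0.123 and 0.248 RPKM in nga, so that its mean was 3.90 (n = 2) in WT and 0.167 ± 0.0702 (SD, n = 3) in nga. In 35S:NGA it stood at 4.15, 4.56 and 3.68 RPKM. NGA3 (AT1G01030, chromosome 1, 11649 to 13714) stood at 5.47 and 4.81 RPKM in WT, at 2.56, 2.65 and 2.97 RPKM in nga, and at 102, 120 and 166 RPKM in 35S:NGA. The mean of NGA3 was 5.14 ± 0.470 (SD, n = 2) in WT and 129 ± 33.2 (SD, n = 3) in 35S:NGA.

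NGA1 (AT2G46870, chromosome 2, 19260906 to 19262533) stood at 23.5 and 23.9 RPKM in WT, at 21.2, 23.7 and 25.6 RPKM in nga, and at 15.6, 21.4 and 12.9 RPKM in 35S:NGA. NGA2 (AT3G61970, chromosome 3, 22951323 to 22953265) stood at 9.50 and 8.15 RPKM in WT, at 9.72, 7.73 and 14.9 RPKM in nga, and at 8.88, 7.47 and 5.78 RPKM in 35S:NGA. The labels give no alleles, and RPKM over a whole gene does not show whether a transcript is intact, so the levels of NGA1 and NGA2 in nga check nothing about their function.

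**Figure D1:**
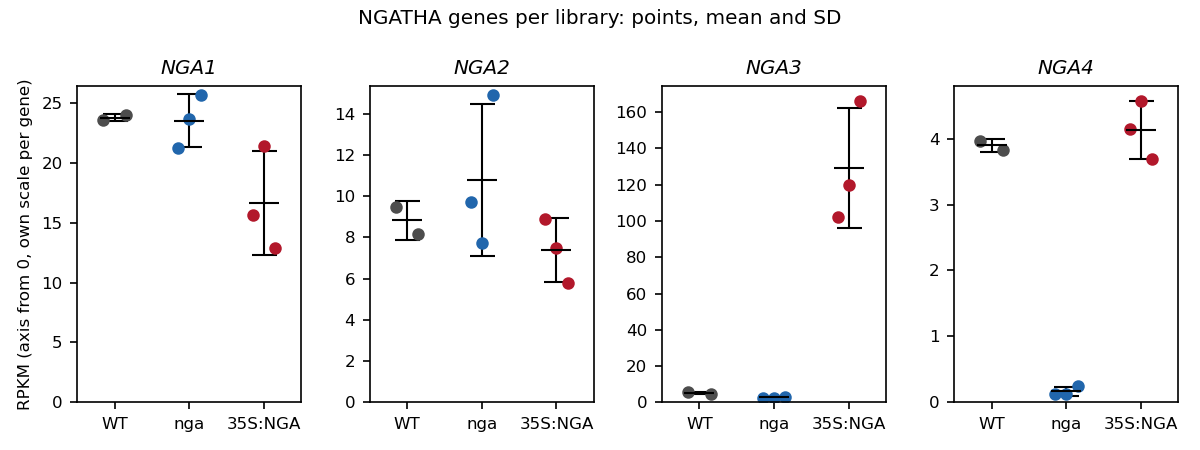
RPKM of the 4 NGATHA genes in each library, with 1 point per library and the mean and SD of each group (n = 2 WT, 3 nga, 3 35S:NGA), on a linear axis from 0 with its own scale for each gene. NGA4 was at or below 0.248 RPKM in the nga libraries and NGA3 was at or above 102 RPKM in the 35S:NGA libraries.

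In nga against WT, NGA4 fell by 2.07 ± 0.15 (adjusted p = 0.00117) and NGA3 fell by 0.72 ± 0.20 (adjusted p = 0.0439). The call of NGA3 was lost without any 1 of WT 1, WT 2, nga 1, nga 2 and 35S:NGA 2, with a highest adjusted p of 0.217. NGA1 differed by -0.02 ± 0.20 and NGA2 by 0.22 ± 0.26, neither past the threshold. In 35S:NGA against WT, NGA3 rose by 4.38 ± 0.20, 20.8-fold (adjusted p = 0.00027), and it kept this call without any single library. NGA1 differed there by -0.51 ± 0.20, NGA2 by -0.24 ± 0.26 and NGA4 by 0.06 ± 0.15, none past the threshold. In 35S:NGA against nga, NGA3 rose by 5.10 ± 0.18, 34.3-fold (adjusted p = 1.09e-05), and NGA4 by 2.13 ± 0.14 (adjusted p = 0.000222). As a list tested with camera, the 4 NGATHA genes were not called against WT in nga (adjusted p = 0.137) or in 35S:NGA (adjusted p = 0.474, where their median of -0.09 and mean of 0.92 differed in sign), nor in 35S:NGA against nga (adjusted p = 0.0922). With fry, which tests a list by itself and not against other genes, the NGATHA list was called in all 3 comparisons, with adjusted p of 0.0118, 0.0112 and 0.000131. The nga label names these genes and NGA3 was raised in 35S:NGA, so calls of this list check the lines alone.

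Library nga 2 stood apart in genes of the circadian clock, which were picked after their values were seen. CCA1, a morning-phased clock transcription factor, was at 132 RPKM in nga 2 and at 0.460 to 2.86 RPKM in the other libraries. Its partner LHY was at 115 RPKM in nga 2 and at 0.482 to 1.19 RPKM elsewhere. The evening-phased genes GRP7, an RNA-binding protein, and ELF4 were at their lowest in nga 2, at 444 and 0.0844 RPKM. The first principal component held 46.2% of the variance and ran from -44.7 and -37.0 in WT through -25.6 to -3.97 in 35S:NGA to 15.6, 39.8 and 65.4 in nga 3, nga 1 and nga 2. The third held 13.2% and set the lane 8 libraries, at -34.7 and -29.0, apart from the others, at 1.62 to 17.9.

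**Figure D2:**
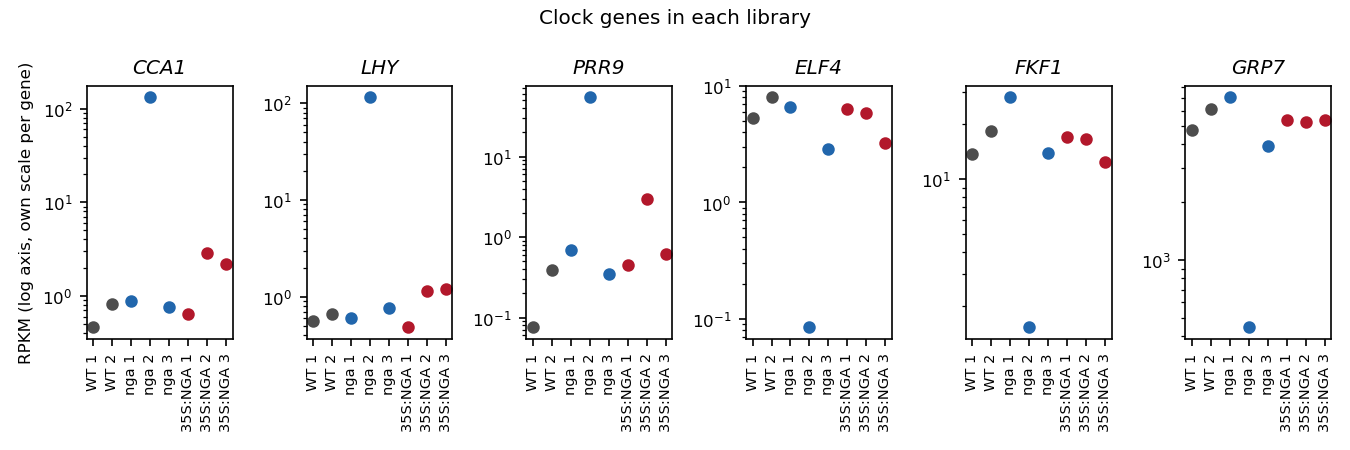
RPKM of 6 clock genes in each library, with 1 point per library on a log axis that has its own scale for each gene. Library nga 2 holds the highest CCA1 (132 RPKM), LHY (115 RPKM) and PRR9 (54.0 RPKM) and the lowest ELF4, FKF1 and GRP7.

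Markers of other organs also differed between libraries. The median of 8 mature pollen markers, as the log2 difference from the WT mean, was -0.40 and 0.40 in WT, 1.03, 0.48 and 0.69 in nga, and 0.42, 1.64 and 1.56 in 35S:NGA. The median of 16 green tissue markers, photosynthesis genes, was within 0.02 of 0 in WT, at 0.49, 0.87 and 0.21 in nga, and at 0.32, 0.33 and 1.47 in 35S:NGA. For 8 tapetum and microspore markers it was 0.28 and -0.28 in WT, -0.38, 0.84 and 0.19 in nga, and 0.54, 0.20 and 0.35 in 35S:NGA. For 16 heat shock and wounding genes it was -0.44 and 0.44 in WT, 0.25, 0.06 and -0.82 in nga, and 0.28, 0.71 and -0.10 in 35S:NGA.

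**Figure D3:**
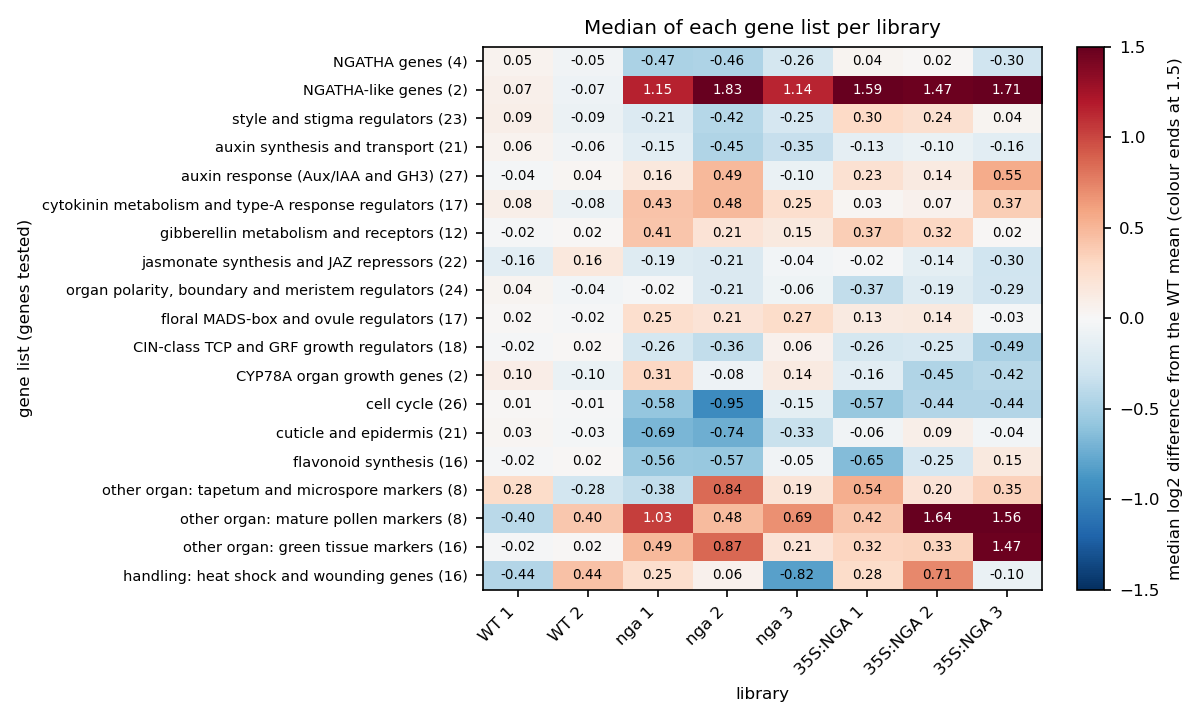
Median log2 difference of RPKM + 1 from the WT mean for each gene list (rows, with the number of genes tested) in each of the 8 libraries (columns), with the value written in each cell and colours that end at 1.5. The mature pollen markers stand highest in 35S:NGA 2 and 35S:NGA 3 and the green tissue markers in 35S:NGA 3.

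The comparison of nga with WT asks which transcripts depend on the NGATHA genes. In nga, 1361 genes fell and 1647 rose, and of these 497 and 574 changed at least 2-fold. Among the genes with the largest falls by the rule for named genes were scpl47 (AT5G22980), a serine carboxypeptidase-like gene, which fell by 4.53 ± 0.42 (adjusted p = 0.00262), and PRP4 (AT4G38770), a proline-rich cell wall protein, which fell by 4.07 ± 0.43 (adjusted p = 0.00497). The gene scpl47 (chromosome 5, 7688027 to 7690652) went from 36.5 and 28.7 RPKM in WT to 0.0579, 0.0775 and 1.65 RPKM in nga, and PRP4 (chromosome 4, 18096606 to 18098633) from 272 and 187 RPKM to 10.4, 8.68 and 21.2 RPKM. ANNAT1 (AT1G35720), an annexin, fell by 3.46 ± 0.28, PR5 (AT1G75040), a thaumatin-like pathogenesis-related gene, fell by 3.37 ± 0.29, and LTP4 (AT5G59310), a lipid transfer protein, fell by 3.28 ± 0.83. The cold-regulated genes COR15A (AT2G42540) and COR15B (AT2G42530) fell by 4.08 ± 1.14 and 3.45 ± 0.78, but they are adjacent, related genes, and whether reads were shared between them was not tested, so their single values are uncertain.

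The gene with the largest rise in nga by the same rule was SEN1 (AT4G35770), a gene known to be induced by darkness and in ageing leaves. SEN1 (chromosome 4, 16944878 to 16946266) went from 1.60 and 1.18 RPKM in WT to 293, 687 and 264 RPKM in nga, a rise of 7.31 ± 0.72 or 159-fold (adjusted p = 0.00359). ASN1 (AT3G47340), an asparagine synthetase induced in the dark, rose by 3.89 ± 0.64, and BCAT-2 (AT1G10070), an aminotransferase of branched-chain amino acids, by 4.87 ± 0.75. GLYI4 (AT1G15380), a glyoxalase I family gene, rose by 4.66 ± 0.59, MIOX4 (AT4G26260), a myo-inositol oxygenase, by 4.25 ± 0.52, J8 (AT1G80920), a chloroplast DnaJ protein, by 4.20 ± 0.71, and HB40 (AT4G36740), a homeodomain-leucine zipper factor, by 4.07 ± 0.80. The NGATHA-like genes NGAL1 (AT2G36080) and NGAL2 (AT3G11580), which encode related B3 factors, rose by 1.85 ± 0.25 and 0.89 ± 0.23, the 2 members of that list.

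Against 3008 calls in nga against WT with all libraries, there were 41 without WT 1, 47 without WT 2, 491 without nga 1, 843 without nga 2 and 5135 without nga 3. Of these, 40, 47, 483, 830 and 2902 were among the 3008. Genes that rose made up 54.8% of the calls, but 48.8% after quantile normalization, 47.9% with the library medians set equal, 49.2% within lane 6, 47.4% with the lane as a term and 47.4% without the lane 8 libraries. Their share was 22.0% without WT 1, 10.6% without WT 2, 48.5% without nga 1 and 47.3% without nga 3, so which direction held more genes is not settled. Within lane 6 alone, with n = 2 in each group, 5562 genes were called, against 6005 with the lane as a term and 6031 without the lane 8 libraries. Of the 56 gene calls named for this comparison, 50 were lost without WT 1, 48 without WT 2, 29 without nga 1, 19 without nga 2, 5 without 35S:NGA 2, 3 without 35S:NGA 1, 2 without 35S:NGA 3 and 1 without nga 3. Those of scpl47, ANNAT1, PR5, SEN1, NGA4 and LOG8 were kept without each single library. Without WT 1 or WT 2 the WT group is 1 library, so in every such fit the spread comes from nga and 35S:NGA alone.

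Among 23 style and stigma regulators, 8 fell and 1 rose in nga, and adjusted over the list alone 8 fell and 2 rose. BEE1 (AT1G18400), a brassinosteroid-induced bHLH factor, fell by 1.73 ± 0.17 (adjusted p = 0.00359), HEC1 (AT5G67060), a bHLH factor of stigma and transmitting tract formation, by 1.25 ± 0.15 (adjusted p = 0.00792), and SRS7 (AT1G19790), of the SHI family of RING-like zinc fingers, by 1.14 ± 0.17 (adjusted p = 0.0125). The others that fell were STY2, SRS5, HEC2, HEC3 and BEE3, and ALC, a bHLH factor of fruit opening, rose. As a list they lay lower in nga (camera, median -0.30, adjusted p = 0.0429). This call was not made by fry (adjusted p = 0.0551) and was lost with the inter-gene correlation estimated from the data (adjusted p = 0.727 with an estimated correlation). It was also lost with the lane as a term (adjusted p = 0.178), without the lane 8 libraries (0.164), with the replicate number as a block (0.165), and without WT 1, nga 3 or 35S:NGA 2 (up to 0.151).

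**Figure D4:**
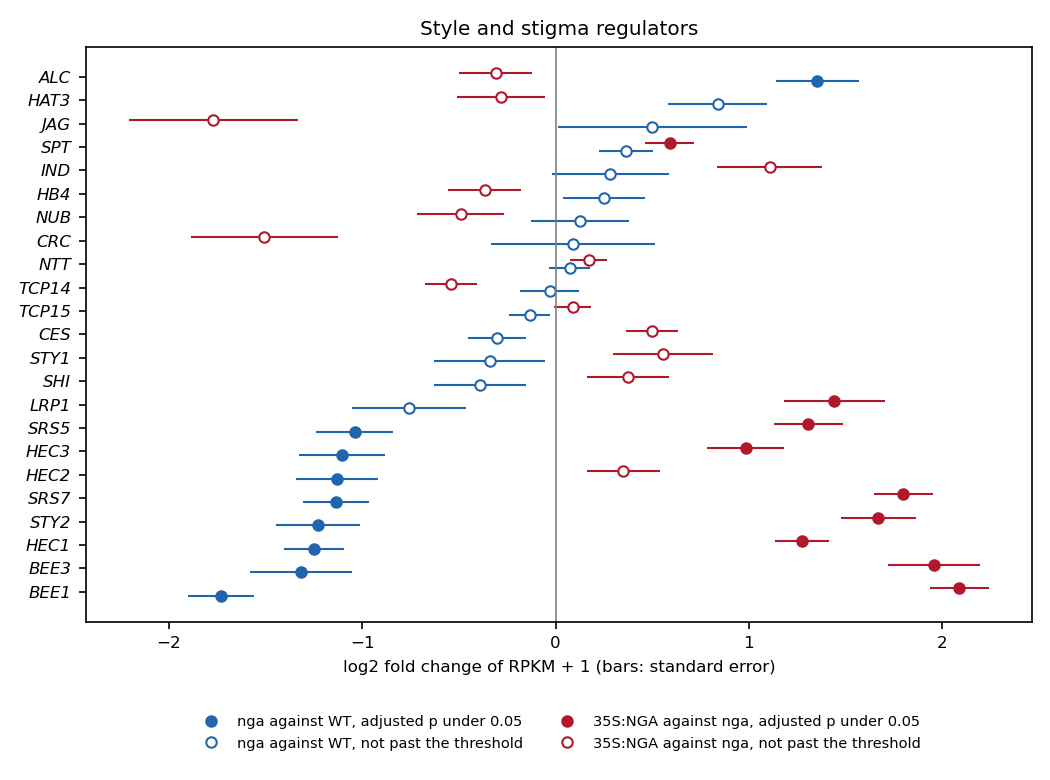
Log2 fold change of RPKM + 1 for the 23 style and stigma regulators in nga against WT (blue) and in 35S:NGA against nga (red), with bars for the standard error from limma and filled points for an adjusted p under 0.05. Of the 8 that fell in nga, 7 rose in 35S:NGA against nga. Both comparisons use the same nga libraries with opposite sign, which favours opposite directions. In 35S:NGA against WT limma called 0 of the 23.

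Auxin genes changed in nga in both directions. Of 21 genes of auxin synthesis and transport, 4 fell, and 4 fell adjusted over the list alone. TAA1 (AT1G70560), a tryptophan aminotransferase of auxin synthesis, fell by 1.29 ± 0.27, YUC4 (AT5G11320), a flavin monooxygenase of the same pathway, by 0.87 ± 0.21, and WAG2 (AT3G14370), a kinase that acts on auxin transporters, by 1.05 ± 0.15, with YUC6 as the other. The list lay lower in nga (camera, median -0.26, adjusted p = 0.0343, and adjusted p = 0.727 with an estimated correlation), and its call was lost with the lane as a term (0.136), without the lane 8 libraries (0.164), with the replicate number as a block (0.134), and without WT 1 or nga 3 (up to 0.151). Of 27 auxin response genes, 3 rose and 1 fell, with the same counts adjusted over the list alone. IAA18 (AT1G51950) rose by 0.86 ± 0.19 and IAA13 (AT2G33310) by 0.53 ± 0.14, and IAA1 (AT4G14560) fell by 1.19 ± 0.17, all Aux/IAA repressors, with no call for the list (adjusted p = 0.787).

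Other hormone lists held few calls in nga. Of 17 cytokinin genes, LOG8 (AT5G11950), of the family that activates cytokinins, fell by 1.92 ± 0.14 (adjusted p = 0.00112), and the type-A response regulators ARR5 (AT3G48100) and ARR9 (AT3G57040) rose by 1.33 ± 0.30 and 1.52 ± 0.38, with the same counts adjusted over the list alone and a list adjusted p of 0.139. That list was called higher without nga 3 (0.0476), with the lane as a term (0.0218) and without the lane 8 libraries (0.0221). Of 12 gibberellin genes, the receptor GID1C (AT5G27320) rose by 1.83 ± 0.34, also adjusted over the list alone (list adjusted p = 0.245). Of 22 jasmonate genes, the repressor JAZ12 (AT5G20900) rose by 0.49 ± 0.14 and the storage protein VSP1 (AT5G24780) fell by 1.82 ± 0.42 (list adjusted p = 0.584). Adjusted over the list alone, 0 jasmonate genes were called by limma, while 3 lay higher and 2 lower at an unadjusted p under 0.05.

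Developmental regulators changed in both directions in nga. Of 24 polarity, boundary and meristem regulators, the knotted-like homeobox genes STM (AT1G62360) and KNAT2 (AT1G70510) rose by 0.74 ± 0.12 and 0.79 ± 0.15, and KNAT1 (AT4G08150) fell by 0.92 ± 0.17. Of 17 floral MADS-box and ovule regulators, 3 rose over all genes and 4 adjusted over the list alone. These 3 were SHP2 (AT2G42830), a carpel identity factor, by 0.63 ± 0.12, PI (AT5G20240), a petal and stamen identity factor, by 0.85 ± 0.18, and INO (AT1G23420), a factor of the ovule's outer integument, by 0.62 ± 0.15. Of 18 CIN-class TCP and GRF growth regulators, 4 rose and 3 fell, with GRF4 (AT3G52910) up by 1.23 ± 0.22, GRF3 (AT2G36400) at -0.76 ± 0.13 and TCP4 (AT3G15030) at -0.92 ± 0.21. The polarity list and the growth regulator list had the same counts adjusted over the list alone, and none of these 3 lists was called (adjusted p = 0.548, 0.112 and 0.559). Of the 2 CYP78A organ growth genes, 0 were called by limma, while 1 lay higher at an unadjusted p under 0.05 and when adjusted over the list alone.

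Among cell cycle, cuticle and flavonoid genes, more fell than rose in nga, and most were not called. Of 26 cell cycle genes, 8 fell and 1 rose, and adjusted over the list alone 10 fell and 1 rose. The falls were CDKB1;1, CDKB1;2 and MCM2 to MCM7, subunits of the helicase that opens DNA for replication, with MCM5 (AT2G07690) at -1.36 ± 0.25 and MCM7 (AT4G02060) at -1.17 ± 0.22, and the D-type cyclin CYCD3;2 (AT5G67260) rose by 1.36 ± 0.21. Of 21 cuticle and epidermis genes, 8 fell and 1 rose, and adjusted over the list alone 10 fell and 1 rose. CER2 (AT4G24510), needed for long wax chains, fell by 1.97 ± 0.27, BDG1 (AT1G64670), an epidermal hydrolase, by 1.21 ± 0.21, and LACS2 (AT1G49430), an acyl-CoA synthetase of cutin synthesis, by 0.95 ± 0.14, and MYB16 rose. Of 16 flavonoid genes, 5 fell, and 8 adjusted over the list alone. F3'H (AT5G07990), FLS1 (AT5G08640) and CHI (AT3G55120), enzymes of flavonoid synthesis, fell by 2.94 ± 0.37, 2.68 ± 0.29 and 1.57 ± 0.16. The 3 lists lay lower in nga by camera, with medians of -0.55, -0.48 and -0.48 and adjusted p of 0.00123, 0.000642 and 0.0272 for cell cycle, cuticle and flavonoid genes, and each had adjusted p = 0.727 with an estimated correlation. With fry the adjusted p of these lists was 0.181, 0.0455 and 0.155. Beside them, per library, the cell cycle median was -0.58, -0.95 and -0.15 in nga 1, nga 2 and nga 3, the cuticle median was -0.69, -0.74 and -0.33, and the flavonoid median was -0.56, -0.57 and -0.05.

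Markers of other organs gave few calls in nga. Of 8 tapetum and microspore markers, the sporopollenin synthesis genes TKPR1 (AT4G35420) and LAP6 (AT1G02050) rose by 1.14 ± 0.23 and 0.88 ± 0.22, also adjusted over the list alone (list adjusted p = 0.516). Of 16 green tissue markers, the photosystem antenna gene LHCA4 (AT3G47470) rose by 1.93 ± 0.55 and 0 were called adjusted over the list alone, while limma put 2 higher at an unadjusted p under 0.05 (list median 0.59, adjusted p = 0.0781). That list was called higher without WT 2 (0.0245), nga 1 (0.0253), nga 3 (0.0444) or 35S:NGA 3 (0.0310), after quantile normalization (0.0323), with the lane as a term (0.00541) and without the lane 8 libraries (0.00410). Of 8 mature pollen markers limma called 0, with 2 higher at an unadjusted p under 0.05 (list median 0.61, adjusted p = 0.188, but 0.0156 without WT 2). Of 16 heat shock and wounding genes it called 0, with 1 higher at an unadjusted p under 0.05 (adjusted p = 0.828, where the median of 0.02 and the mean of -0.06 differed in sign).

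The comparison of 35S:NGA with WT asks what a gain of NGATHA expression changed. Here 15 genes rose and 12 fell, of which 13 and 12 by at least 2-fold, while 3629 genes had an unadjusted p under 0.05 by limma. The nga libraries entered this comparison only through the pooled spread and the filter on low values. With only the 2 groups compared, limma called 328 genes here and 1711 in nga against WT. The counts of 27 and 3008 thus do not measure the relative size of the changes. FUL (AT5G60910), a MADS-box factor of the fruit valves, fell by 2.52 ± 0.28 (adjusted p = 0.0259). FUL (chromosome 5, 24502434 to 24506269) stood at 89.5 and 76.3 RPKM in WT, at 149, 123 and 116 RPKM in nga and at 18.5, 15.7 and 8.59 RPKM in 35S:NGA. The YABBY genes YAB5 (AT2G26580) and YAB3 (AT4G00180), factors of the abaxial side of organs, fell by 2.49 ± 0.28 and 1.73 ± 0.20. GDU2 (AT4G25760), a glutamine export gene, fell by 2.43 ± 0.19, and TCL1 (AT2G30432), an R3-type MYB that represses trichomes, also fell (adjusted p = 0.0451).

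Besides NGA3, the largest rises in 35S:NGA among called genes, by the rule for named genes, were those of SEN1, HB21 and UBC17. SEN1 rose by 5.52 ± 0.72 (adjusted p = 0.0451). HB21 (AT2G18550), a homeodomain-leucine zipper factor, rose by 2.65 ± 0.23 (adjusted p = 0.00713), and UBC17 (AT4G36410), a ubiquitin-conjugating enzyme, by 2.33 ± 0.20. SEN1 stood at 205, 35.2 and 173 RPKM in 35S:NGA. GASA6 (AT1G74670), a gibberellin-regulated peptide, rose by 1.92 ± 0.24, NGAL1 by 1.87 ± 0.25, and JP630 (AT1G23760), a BURP-domain protein, by 1.71 ± 0.14. SEN1, HB21, UBC17 and NGAL1 were also higher in nga than in WT. Of the 2 NGATHA-like genes, NGAL1 was called over all genes and both were called adjusted over the list alone.

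Against 27 calls in 35S:NGA against WT with all libraries, there was 1 without WT 1 and 1 without WT 2, and there were 13 without nga 1, 205 without nga 2, 284 without nga 3, 10 without 35S:NGA 1 and 11 without 35S:NGA 2. Of these, 1, 1, 12, 27, 27, 10 and 10 were among the 27. With the lane as a term there were 14, of which 2 were among the 27. Without the lane 8 libraries there were 334, which held all 27, but there lane and genotype cannot be told apart. Genes that rose made up 55.6% of the calls, but 35.1% after quantile normalization (26 of 74), 42.4% with the library medians set equal (14 of 33), 45.5% with the replicate number as a block (10 of 22) and 48.5% with a pseudocount of 5 (16 of 33). Of the 13 gene calls named for this comparison, 12 were lost without WT 1, 12 without WT 2, 7 without nga 1, 6 without 35S:NGA 1, 5 without 35S:NGA 2 and 5 without 35S:NGA 3. The replicate number as a block ended 8, and 9 of its 22 calls were among the 27. The lane as a term ended 11, but in that fit 35S:NGA enters only through 35S:NGA 3 set against nga 3. Calls made or lost there rest on 1 35S:NGA library and are no correction for lane.

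Of the 24 polarity, boundary and meristem regulators, YAB3 and YAB5 fell in 35S:NGA, and adjusted over the list alone 8 fell and 3 rose. The list lay lower (camera, median -0.27, adjusted p = 0.0005), with adjusted p = 0.519 with an estimated correlation. FUL was the member of the 17 floral MADS-box and ovule regulators that fell, also adjusted over the list alone (list adjusted p = 0.714, where the median of 0.14 and the mean of -0.07 differed in sign). Of 23 style and stigma regulators limma called 0, with 6 higher and 4 lower at an unadjusted p under 0.05, and adjusted over the list alone 4 rose and 3 fell (list adjusted p = 0.180). SPT, a bHLH factor of the carpel margins, differed by 0.95 ± 0.14 with an adjusted p of 0.0505.

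Auxin and growth lists were called in 35S:NGA against WT without calls of single genes. Of 21 genes of auxin synthesis and transport limma called 0, with 1 higher and 6 lower at an unadjusted p under 0.05 and the same counts adjusted over the list alone. That list lay lower (median -0.17, adjusted p = 0.0233, and adjusted p = 0.519 with an estimated correlation) but not without nga 3 or 35S:NGA 3 (up to 0.0690), with the lane as a term (0.290), without the lane 8 libraries (0.124) or with the replicate number as a block (0.0689). Of 27 auxin response genes limma called 0, with 5 higher at an unadjusted p under 0.05 and 4 adjusted over the list alone. They lay higher (median 0.35, adjusted p = 0.00482, and adjusted p = 0.519 with an estimated correlation) but not without 35S:NGA 3 (0.0583) or without the lane 8 libraries (0.0633). Of 18 CIN-class TCP and GRF growth regulators limma called 0, with 2 higher and 5 lower at an unadjusted p under 0.05 and 3 lower adjusted over the list alone. They lay lower (median -0.30, adjusted p = 0.00711, and adjusted p = 0.519 with an estimated correlation) but not without 35S:NGA 3 (0.0583) or, just above the threshold, without the lane 8 libraries.

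The 26 cell cycle genes lay lower in 35S:NGA than in WT, 25 of them with a negative difference (median -0.53, adjusted p = 4.51e-07, and adjusted p = 0.519 with an estimated correlation). Among them limma called 0, over all genes and adjusted over the list alone, with 9 lower at an unadjusted p under 0.05. The 21 cuticle genes (adjusted p = 0.687) and the 16 flavonoid genes (adjusted p = 0.180, but 0.0308 and lower without 35S:NGA 3) were not called as lists. Limma called 0 of either, with 3 cuticle and 4 flavonoid genes lower at an unadjusted p under 0.05, and adjusted over the list alone 2 flavonoid genes fell. Cytokinin genes (adjusted p = 0.856, where the median of -0.01 and the mean of 0.09 differed in sign), gibberellin genes (0.171, but 0.0472 and higher without WT 2) and jasmonate genes (0.297, but 0.0418 and lower without WT 1) were not called either. Limma called 0 genes of these 3 lists, with 3 cytokinin, 2 gibberellin and 2 jasmonate genes higher and 3 cytokinin and 2 jasmonate genes lower at an unadjusted p under 0.05. Adjusted over the list alone, 1 cytokinin gene rose and 1 jasmonate gene fell. With the lane as a term, 35S:NGA enters only through 35S:NGA 3 set against nga 3. In that setting the cytokinin list was called higher (0.00707) and the jasmonate list lower (0.00948). With the replicate number as a block the gibberellin list was called higher (0.0456) and the flavonoid list lower (0.00942). The CYP78A genes gave 0 calls by limma, with 1 lower at an unadjusted p under 0.05, and 0 adjusted over the list alone.

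Mature pollen and green tissue markers were called higher as lists in 35S:NGA beside these changes. The 8 mature pollen markers were all above their WT means (median 1.23, adjusted p = 0.00163, and adjusted p = 0.519 with an estimated correlation). Limma called 0 of them over all genes, with 6 higher at an unadjusted p under 0.05 and adjusted over the list alone. Of the 16 green tissue markers 15 were above their WT means (median 0.68, adjusted p = 0.00683, and adjusted p = 0.684 with an estimated correlation), a call lost without 35S:NGA 3 (0.168), without the lane 8 libraries (0.0823) and with the replicate number as a block (0.0689), and limma called 0 of them with 2 higher at an unadjusted p under 0.05. The 8 tapetum and microspore markers (median 0.31, adjusted p = 0.0815, but 0.00462 without WT 1) and the 16 heat shock and wounding genes (median 0.48, adjusted p = 0.180, but 0.00124 without WT 2, 0.00555 with the lane as a term and 0.00942 with the replicate number as a block) were not called as lists. Limma called 0 of them, with 3 and 2 higher at an unadjusted p under 0.05, and adjusted over the list alone 3 tapetum and microspore markers rose.

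The comparison of 35S:NGA with nga sets gain against loss and does not use the WT libraries in its difference. In 35S:NGA, 661 genes rose and 288 fell against nga, of which 423 and 103 by at least 2-fold. After NGA3, the largest rises by the rule for named genes were those of PRP4, scpl47, SBT5.4 and EXPA8. PRP4 rose by 4.87 ± 0.39 (adjusted p = 0.000545) and scpl47 by 4.79 ± 0.37 (adjusted p = 0.000528). SBT5.4 (AT5G59810), a subtilisin-like protease, rose by 4.16 ± 0.28, and EXPA8 (AT2G40610), an expansin of the cell wall, by 3.75 ± 0.44. PRP4 stood at 492, 517 and 240 RPKM in 35S:NGA and scpl47 at 51.8, 40.6 and 27.8 RPKM. FUL fell by 3.15 ± 0.25 (adjusted p = 0.000561). CORI3 (AT4G23600), a jasmonate-responsive cystine lyase, fell by 3.09 ± 0.53, THA1 (AT1G08630), a threonine aldolase, by 2.61 ± 0.34, ASN1 by 2.54 ± 0.57, and CYP79B3 (AT2G22330), a cytochrome P450 of indole glucosinolate synthesis, by 2.53 ± 0.55.

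Against 949 calls in 35S:NGA against nga with all libraries, there were 583 without WT 1, 582 without WT 2, 360 without nga 1, 478 without nga 2, 2517 without nga 3 and 355 without 35S:NGA 2. Of these, 574, 573, 349, 444, 937 and 349 were among the 949. With the lane as a term there were 145, with 114 of them among the 949, which by construction rest on 35S:NGA 3 and nga 3 alone. Without the lane 8 libraries there were 2071, but there 35S:NGA and nga share no lane. Of the 39 gene calls named for this comparison, 6 were lost without WT 1, 6 without WT 2, 10 without nga 1, 9 without nga 2, 8 without 35S:NGA 1, 13 without 35S:NGA 2 and 8 without 35S:NGA 3, and the lane as a term ended 24. The 26 calls kept without each single library included those of NGA3, NGA4, PRP4, scpl47, FUL, BEE1, SRS7, HEC1 and LOG8.

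Of the 23 style and stigma regulators, 9 rose in 35S:NGA against nga, and adjusted over the list alone 11 rose and 3 fell. BEE1 rose by 2.09 ± 0.15 (adjusted p = 0.000414), SRS7 by 1.80 ± 0.15 (adjusted p = 0.00074) and HEC1 by 1.27 ± 0.14 (adjusted p = 0.00242), and STY2, SRS5, LRP1, HEC3, SPT and BEE3 were the others. The list lay higher (camera, median 0.50, adjusted p = 0.00107), also without each single library, with adjusted p = 0.481 with an estimated correlation.

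Auxin genes differed between 35S:NGA and nga in both directions. Of 21 genes of auxin synthesis and transport 4 rose and 1 fell, and 6 and 4 adjusted over the list alone. WAG2 rose by 1.19 ± 0.13 and PIN3 (AT1G70940), an auxin efflux carrier, by 0.89 ± 0.15, and TAR2 (AT4G24670), a tryptophan aminotransferase related to TAA1, fell by 0.96 ± 0.17. The list was not called (adjusted p = 0.993, where the median of -0.14 and the mean of 0.06 differed in sign). Of 27 auxin response genes 5 rose and 1 fell, and 6 and 1 adjusted over the list alone, with the Aux/IAA genes IAA1, IAA19 (AT3G15540) and IAA7 (AT3G23050) up, IAA1 by 1.99 ± 0.15 and IAA19 by 1.33 ± 0.19 (list adjusted p = 0.0864, but 0.00122 without nga 2, 0.0207 without 35S:NGA 2 and 1.48e-07 with the lane as a term). Of 17 cytokinin genes LOG8 rose by 2.54 ± 0.12 (adjusted p = 8.4e-05) and CKX1 (AT2G41510), a cytokinin oxidase, fell by 0.77 ± 0.16, and adjusted over the list alone 1 rose and 4 fell. That list lay lower (median -0.52, adjusted p = 0.0347, and adjusted p = 0.481 with an estimated correlation) but not without nga 1, nga 2 or 35S:NGA 1 (up to 0.0788), with the replicate number as a block (0.0646) or with the lane as a term, where its direction turned (0.504). Of 22 jasmonate genes the repressor JAZ1 (AT1G19180) rose by 0.87 ± 0.17, also adjusted over the list alone (list adjusted p = 0.817, but 0.0148 and lower with the lane as a term). Of 12 gibberellin genes limma called 0, with 1 higher and 1 lower at an unadjusted p under 0.05 (list adjusted p = 0.935).

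Among polarity genes, more fell than rose in 35S:NGA against nga, and most were not called. Of the 24 polarity, boundary and meristem regulators 6 fell and 1 rose, and 8 and 2 adjusted over the list alone. YAB2 (AT1G08465) fell by 1.85 ± 0.21 and STM by 0.93 ± 0.10, with FIL, YAB3, YAB5 and AS1 as the others, and KNAT1 rose by 1.47 ± 0.16. The list lay lower (median -0.29, adjusted p = 0.00473, and adjusted p = 0.481 with an estimated correlation). Of 17 floral MADS-box and ovule regulators FUL and SHP2, the latter by 0.54 ± 0.11, fell, and adjusted over the list alone 4 fell and 1 rose (list adjusted p = 0.0953, but 0.0429 without nga 2, 0.0371 without 35S:NGA 2 and 0.00022 with the lane as a term). Of 18 CIN-class TCP and GRF growth regulators 3 fell and 1 rose, and 5 and 2 adjusted over the list alone. GRF4 fell by 2.07 ± 0.20 and GIF1 (AT5G28640), a coactivator of GRF factors, by 1.34 ± 0.27, and TCP5 (AT5G60970) rose by 1.19 ± 0.16 (list adjusted p = 0.0953, but 0.0125 without nga 2, 0.0371 without 35S:NGA 2 and 0.000439 with the lane as a term). The NGATHA-like genes gave 0 calls by limma, with 0 at an unadjusted p under 0.05. CYP78A5 (AT1G13710), a cytochrome P450 that promotes organ growth, fell by 0.94 ± 0.15, also adjusted over the list alone.

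Some cuticle and flavonoid genes rose in 35S:NGA against nga, and most were not called. Of 21 cuticle and epidermis genes 5 rose, and adjusted over the list alone 10 rose and 1 fell. CYP86A4 (AT1G01600) and CYP77A6 (AT3G10570), cytochromes P450 of cutin synthesis, rose by 2.34 ± 0.28 and 1.06 ± 0.15, and BDG1 by 1.41 ± 0.18. The list lay higher (median 0.46, adjusted p = 3.64e-05, and adjusted p = 0.481 with an estimated correlation). Of 16 flavonoid genes F3'H rose by 2.55 ± 0.33 and FLS1 by 1.42 ± 0.26, and 4 rose adjusted over the list alone. That list lay higher (median 0.35, adjusted p = 0.0117, and adjusted p = 0.626 with an estimated correlation) but not without nga 1 or 35S:NGA 3 (up to 0.0678). Of 26 cell cycle genes CYCD3;2 fell by 1.13 ± 0.19, also adjusted over the list alone (list adjusted p = 0.993, where the median of -0.04 and the mean of 0.09 differed in sign, but 0.0173 and lower with the lane as a term).

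Markers of other organs were not called as lists between 35S:NGA and nga. Of 8 tapetum and microspore markers GRP17 (AT5G07530), a protein of the pollen coat, rose by 1.00 ± 0.19 and QRT3 (AT4G20050), a polygalacturonase of pollen separation, by 0.93 ± 0.17, and adjusted over the list alone 2 rose and 1 fell (list adjusted p = 0.817). Limma called 0 of the mature pollen, green tissue and heat shock and wounding genes, with 1, 0 and 2 higher at an unadjusted p under 0.05. The adjusted p of these lists was 0.0953, 0.877 and 0.0953, with calls of higher pollen markers without 35S:NGA 1 (0.00346) and of higher heat shock and wounding genes without nga 2 (0.0186) and with the replicate number as a block (0.0279). Without the lane 8 libraries, where 35S:NGA and nga share no lane, the green tissue markers were called in the opposite direction (0.0113). With the lane as a term, where the comparison rests on 35S:NGA 3 and nga 3 alone, the green tissue markers (1.15e-08), the mature pollen markers (0.0161) and the heat shock and wounding genes (0.000817) were called higher.

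Opposite changes in loss and gain of function were read from genes called in both comparisons against WT. There were 15 such genes, of which 10 were higher in both, 2 were lower in both and 3 went opposite ways, where independent lists would share 1.39, 0.918 and 2.26. NGA3 and GASA6 were lower in nga and higher in 35S:NGA. The nga label names NGA3, which was also the NGATHA gene raised in 35S:NGA, so its opposite call may come from the lines themselves. GASA6 (chromosome 1, 28053030 to 28054149) stood at 10 and 6.26 RPKM in WT, at 2.14, 2.12 and 3.39 RPKM in nga and at 32.9, 39.1 and 27.4 RPKM in 35S:NGA, a fall of 1.35 ± 0.24 and a rise of 1.92 ± 0.24. AT5G16030, which has no symbol, went the other way, with 32.4 and 25.0 RPKM in WT, 77.0, 68.3 and 65.1 RPKM in nga and 5.13, 3.97 and 2.58 RPKM in 35S:NGA. The count of 3 opposite calls became 0 without WT 1, WT 2 or nga 1, 6 without nga 2, 19 without nga 3, 1 without 35S:NGA 2 and 23 without the lane 8 libraries. The count of 0 is of genes called in both comparisons with opposite signs. Without nga 1 limma still called 491 genes in nga against WT and 13 in 35S:NGA against WT, with 5316 and 3192 at an unadjusted p under 0.05. Independent lists would share 4.82 opposite calls without nga 2, 41.6 without nga 3, 0.698 without 35S:NGA 2 and 58.0 without the lane 8 libraries. The counts of 19 and 23 thus lay below that number.

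Across all 17786 genes, which are not independent replicates, the fold changes of nga and 35S:NGA against WT went the same way for 75.6%, with Pearson's r 0.618, Spearman's rho 0.641 and a covariance of 0.185. Simulated unchanged groups that share the WT libraries, with each gene drawn independently, gave 70.5%, r 0.6 and a covariance of 0.0377 over 100 draws. With a different WT library for each group the covariance was 0.178 and 0.148.

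**Figure D5:**
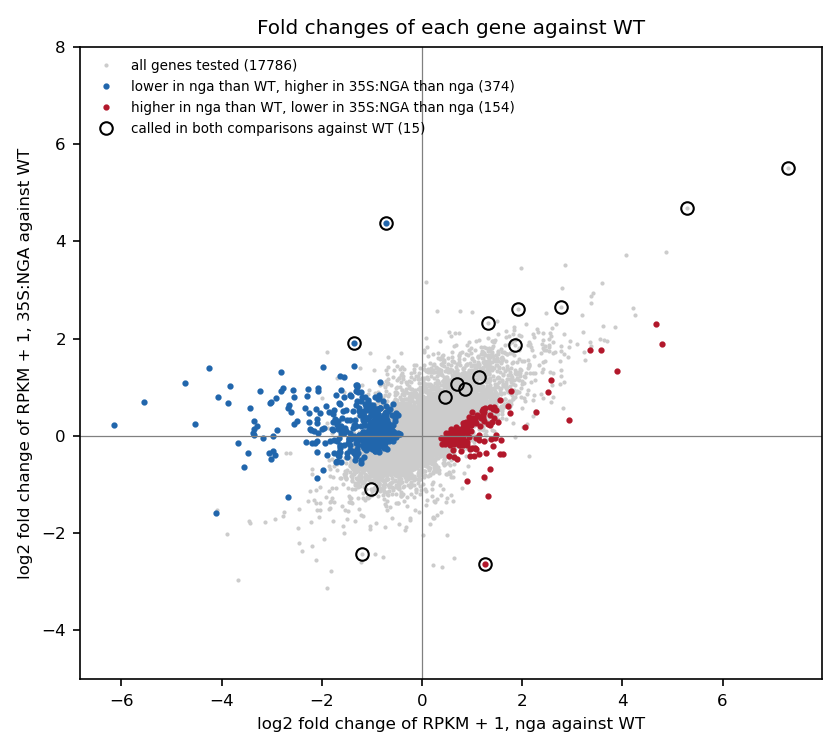
Log2 fold change of RPKM + 1 in nga against WT (horizontal) and in 35S:NGA against WT (vertical) for each of 17786 genes, with circles around the 15 genes called in both. Blue points are the 374 genes lower in nga than in WT and higher in 35S:NGA than in nga, and red points are the 154 genes that were higher and then lower.

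Many genes changed in nga differed the other way between 35S:NGA and nga. Among genes called in nga against WT and in 35S:NGA against nga, 374 were lower in nga and higher in 35S:NGA than in nga, where independent lists would share 50.6, and 154 were higher in nga and lower in 35S:NGA than in nga, where they would share 26.7. The first set included NGA4, which the nga label names, so that its fall may be part of the genotype itself. It also included PRP4, scpl47, BEE1, HEC1, SRS7, WAG2, IAA1, LOG8, BDG1, FLS1 and F3'H, and the second set GRF4, STM, SHP2, CYCD3;2 and ASN1. The remaining 2 genes called in both went 1 each in the other directions. The fold changes had r -0.672 and a covariance of -0.213 across genes. Simulated unchanged groups that share the nga libraries gave r -0.447 and a covariance of -0.0251, with 0 genes called in both by limma in 100 draws. No gene was changed in those groups, so hardly any call could arise and that count is no measure for the overlap. A gene changed in nga alone, with 35S:NGA at the WT level, would fall in the same sets. Each gene was drawn independently in the simulation, so shifts shared by many genes of a library were left out and chance overlap may be understated. With the lane as a term the fold changes had r -0.184 and a covariance of -0.0723. In that setting nga against WT rests on lane 6 and 35S:NGA against nga on lane 8, so no library is shared and the simulated values do not apply.

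The counts of 374 and 154 genes became 31 and 3 without WT 1, 42 and 2 without WT 2, 129 and 22 without nga 1, 167 and 33 without nga 2, and 1104 and 740 without nga 3. They were 195 and 31 without 35S:NGA 2, and the second count was 102 without 35S:NGA 3. With only the 2 groups compared they were 230 and 57, where independent lists would share 17.2 and 8.30. With the lane as a term they were 78 and 14, where independent lists would share 18.0 and 7.04. Without the lane 8 libraries, where 35S:NGA and nga share no lane, they were 1002 and 527.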

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

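The lane settings and equal medians were chosen after the data were seen, and the cause of the shifts was not tested. Without the lane 8 libraries 35S:NGA shares no lane with WT or nga, so its counts there may hold lane effects. Genes changed in nga against WT numbered 3008, and 1711 with only the 2 groups compared, 1071 with at least 2-fold, 6005 with the lane term, 5562 in lane 6 only and 6031 without the lane 8 libraries. Genes changed in 35S:NGA against WT numbered 27, and 74 with quantile normalization, 58 with a filter at a mean of 5 RPKM, 328 with only the 2 groups compared, 81 with a pseudocount of 0.1, 14 with the lane term and 334 without the lane 8 libraries. Genes changed in 35S:NGA against nga numbered 949, and 577 with only the 2 groups compared, 526 with at least 2-fold, 145 with the lane term and 2071 without the lane 8 libraries. Genes changed in opposite directions in nga and 35S:NGA numbered 3, and 5 with quantile normalization, 5 with a filter at a mean of 5 RPKM, 9 with only the 2 groups compared and 23 without the lane 8 libraries. Independent lists would share 2.26, 6.36, 6.02, 15.5 and 58.0 such genes in these settings. Leaving out 1 library gave 41 to 5135 genes in nga against WT, 1 to 284 in 35S:NGA against WT, 355 to 2517 in 35S:NGA against nga and 0 to 19 in opposite directions. Of the list directions, that of the cytokinin metabolism and type-A response regulators in 35S:NGA against nga turned with the lane term (adjusted p = 0.504), and that of the green tissue markers turned without the lane 8 libraries (0.0113). None of the 17 list calls was kept with an estimated correlation, and fry kept 1 of 5 in nga against WT, 0 of 7 in 35S:NGA against WT and 3 of 5 in 35S:NGA against nga. With the lane term 2 of 12, 3 of 10 and 8 of 12 uncalled lists were called.

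With the replicate number as a replicate block the counts were 3892, 22 and 1092 genes, with 4 in opposite directions. The block ended 2 of 5, 2 of 7 and 1 of 5 list calls and called 0, 3 and 1 further lists. The deviations of equally numbered libraries from their group means had r from -0.260 (WT 1 with nga 1) to 0.367 (WT 2 with 35S:NGA 2). With 2 or 3 libraries in a group, whose deviations cancel out, these values cannot show whether the numbers pair the samples.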

Other observations

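Gene families were read from 181 shared gene descriptions with at least 10 tested genes, a grouping chosen after the results were seen. In 35S:NGA against nga, 12 families were called by camera. Besides DUF784, those with the lowest adjusted p were peroxidases, which lay higher (18 genes, median 1.02, 7 rose, adjusted p = 1.06e-08), as did lipid-transfer proteins and related inhibitors (36 genes, median 0.49, 7 rose and 1 fell), inhibitors of invertase and pectin methylesterase (18 genes, median 0.77, 7 rose) and GDSL lipases (45 genes, median 0.39, 8 rose and 1 fell). A second description of invertase and pectin methylesterase inhibitors, with 31 genes, was not among these 12. It lay higher in 35S:NGA against WT (median 0.60), with no gene past the threshold. The DUF784 family, small proteins of unknown function, lay higher in 35S:NGA against WT (25 genes, median 1.23, adjusted p = 1.93e-11, with no gene past the threshold) and against nga (median 1.03, 3 rose). With an estimated correlation none of these families was called (adjusted p = 0.934 against nga and 0.793 against WT).

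The prediction for the genes of starvation was written after the rise of SEN1, ASN1 and BCAT-2 was seen and before their own values were looked up, though some of them may have stood among the most changed genes seen earlier. A sugar starvation or dark response may account for part of the rise in nga. Of 18 further genes known to rise in starvation or darkness, 13 rose in nga, with a median of 1.79 that stood at percentile 100 of 10000 random lists (95th percentile 0.20). Random lists do not carry the joint regulation of such genes, so the percentile overstates how rare such a median is for genes that move together. DIN10 rose by 2.39 ± 0.49 and AKINBETA1 by 2.83 ± 0.52. All 18 lay above the WT mean in 35S:NGA too (median 1.26), none past the threshold. Their mean log2 level was 5.35, 6.19 and 5.09 in nga and 5.49, 4.60 and 5.06 in 35S:NGA, against 3.95 and 3.73 in WT. Without nga 2, 7 rose in nga (median 1.40) and 3 in 35S:NGA (median 1.26). No random lists were drawn for 35S:NGA, so a response there was not tested in the same way.

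For the shift of nga and 35S:NGA the same way from WT, the tests on shared WT libraries and on lanes were chosen only after the result was seen. Chance values that differ between WT 1 and WT 2 are less likely to account for all of the shift. The covariance with a different WT library for each group was at least 0.148, against at most 0.0412 in simulated unchanged groups that share both WT libraries. Each gene was drawn independently in those groups, so chance is not excluded for shifts shared by many genes. A deviation that WT 1 and WT 2 have in common stays in both fold changes, so this test cannot speak to it. A lane difference unrelated to the change in nga is also less likely, as nga 1 and nga 2, in the lane of WT, kept a covariance of at least 0.166 with 35S:NGA 1 and 35S:NGA 2. All 35S:NGA libraries ran outside the lane of WT, so a lane difference that resembled the change in nga stays open. Collection of WT at another time of day stays open. Morning minus evening clock genes differed by 2.55 in nga and 0.27 in 35S:NGA, but without nga 2 the morning genes CCA1 and LHY had a median of 0.11 in nga, while 7 further morning genes had a median of 0.66 in nga and 0.84 in 35S:NGA and 6 further evening genes, which would have to move the other way, had 0.29 and 0.06.

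For the clock genes of nga 2, the tests on genotype were chosen only after the result was seen. Collection of nga 2 at another time of day is a possible explanation, as 13 of 14 further clock genes stood at their extreme in nga 2. Clock genes would move together whatever shifted them, so this count does not tell another time of day from another cause. Another genotype in nga 2 is less likely, as NGA4 stood at 3.15% of its WT mean. An effect of the nga genotype on the clock is also less likely, as CCA1 reached at most 0.875 RPKM in nga 1 and nga 3.

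For the mature pollen markers, the test on anther tissue was chosen only after the result was seen. Pollen carried over with the carpels is a possible explanation, as 18 further pollen genes followed the markers over the 8 libraries (Pearson's r 0.953, Spearman's rho 0.905, n = 8, exact permutation p = 0.00126, adjusted over 2 relations 0.00253). Without the 2 libraries farthest out r was 0.959. Pollen genes would move together whatever raised them, so this relation does not tell carried-over pollen from another source of their transcripts. Anther wall or young anther tissue stays open, as the tapetum and microspore markers had r -0.284 with the pollen markers, within its spread (n = 8, rho -0.262 with exact permutation p = 0.536).

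For the place of nga 3 nearer to WT, at 61.3% of the way from WT to nga 1 and nga 2, the tests on WT mixing and lane 8 were chosen only after the result was seen. NGA4 in nga 3 stood at 6.37% of its WT mean, nga 3 stood at 61.1% of the way over 2438 genes at a high mean, and 35S:NGA 3 stood 5.56 percentage points farther from WT than the mean of 35S:NGA 1 and 35S:NGA 2, which stood at 50.1% and 29.1% of the way. The shift of 35S:NGA 3 is the opposite way to that of nga 3 and within that spread, so it decides nothing.

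For the number of genes called in 35S:NGA against nga, the test on other splits was chosen only after the result was seen. Of the 10 splits of the 6 libraries only 1, the real one, called 949 genes and the highest other called 0 by limma, though up to 3177 genes had an unadjusted p under 0.05 there. With 10 splits a share under 0.05 cannot be reached, so a grouping by chance cannot be told apart from an effect of genotype by this test.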
